A study of Mus musculus with 66 samples.

How the data were processed

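RNA was sequenced from mouse embryonic stem cells of the E14 line, wildtype (3 libraries) or carrying a deletion at Praf2 (4 libraries, numbered by the labels as GDel1 and GDel2 with 2 libraries each). Per the labels, cells grew in serum with LIF and inhibitors of GSK and MEK, and total RNA was depleted of ribosomal RNA and made into strand-marked libraries. The strand used for counting and the annotation release are not given in the sources used here. The other 59 of the 66 samples of the series (binding, R-loop, chromatin contact and drug-treated samples) are not analysed here.

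Each library has 1 deposited table of RSEM gene results. It holds expected counts, which the authors' tool estimated per gene without scaling for depth, with a share of values that are not whole. The deposited tables also hold TPM, scaled by the authors over each gene's effective length and to a fixed sum per library. The deposited FPKM values, per kilobase of effective length, scaled for library size by the authors, were not used. The deposited lengths and effective lengths per gene are in bases. The authors' processing notes name STAR, RSEM, Bowtie2, deepTools and HiC-Pro without versions, and the mm10 genome build. Of 55487 Ensembl gene identifiers, 55141 had a symbol in the table of gene names. Positions came from a RefSeq table of the GRCm38.p6 assembly, matched by symbol.

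Depth ranged from 12316853 to 18762704 expected counts per library. Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR with the 3 groups (minimum count 10, minimum total 15), which left 15421 genes holding 99.9% of the counts, 13903 of them with a position. Fits used R 4.3.3, edgeR 4.0.16 with TMM scaling and the robust quasi-likelihood F test, and the Benjamini-Hochberg method over all genes tested, with an adjusted p under 0.05 as the threshold. All adjusted p values of single genes come from edgeR unless another tool is named. GDel1 against wildtype, GDel2 against wildtype and GDel2 against GDel1 were contrasts of 1 fit with 3 groups. The genotype label is shared by GDel1 and GDel2, so both were also compared with wildtype as 1 group of 4 in a fit with 2 groups, in which the spread between GDel1 and GDel2 counts as error. Values per library are CPM, normalised counts scaled by the TMM library size. Tests were 2-sided unless stated.

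Lists of genes were written before the data were examined, as were the comparisons, the rule for named genes and the alternatives, apart from those named as later in the closing section. The 26 lists were naive pluripotency, formative and primed pluripotency, 2-cell-like genes, primitive endoderm, mesendoderm, neuroectoderm, trophoblast, germline, fibroblast feeder markers, Wnt targets, genes responsive to ERK, p53 targets, the integrated stress and ER stress response, interferon response, hypoxia and glycolysis, cholesterol synthesis, imprinted genes, Hox genes, clustered protocadherins, histones, ribosomal proteins, mitochondrially encoded genes, nuclear RNAs, factors of CTCF and cohesin, factors of R-loops and G-quadruplexes, and genes around Praf2. Each was tested in 3 comparisons with camera of limma 3.58.1 (competitive test, preset correlation of 0.01, log2 CPM with a prior count of 2), with Benjamini-Hochberg adjustment over 78 tests, and again with a correlation estimated per list. Genes of each chromosome were tested in the same way over 42 tests. The lists alone were also tested with fry of limma, adjusted over the same 78 tests. It asks whether a list changed at all, not whether it changed more than other genes. Each list also has a count of its genes past the threshold when p values were adjusted over the list alone.

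The rule for named genes took Praf2, every measured gene within 200 kb of it, the 10 largest rises and falls for the deletion group (none passed), and the 5 largest rises and 5 largest falls of each other comparison among genes past the threshold. Those had a mean of at least 2 CPM in the higher group, groups that did not overlap, and an established symbol. From each list it took up to 4 members past the threshold for the deletion group or, failing these, the 2 of highest expression. This gave 92 genes. The result for some of them is not reported here. Other genes named as members of lists, shared calls and chromosomal segments were chosen after their values were seen.

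A gene at 0 counts in every library of a group was given a bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with its 95% Poisson interval, as was Ddx3y (4 counts) in GDel2 against wildtype. Shares of counts have 95% Wilson intervals. Intervals and floors cover counting error only. The fits were tested on simulated data with changes of known size. The base for all groups was the wildtype mean, so GDel1 and GDel2 did not differ from each other. Of genes set 2-fold apart, 57.6% in GDel1, 56.0% in GDel2 and 64.8% in the deletion group were recovered, with 0 of wrong sign. These were 288, 280 and 324 genes over 5 simulations, beside 417, 406 and 439 recovered at 4-fold. Genes set unchanged were also called, 68 in GDel1, 73 in GDel2 and 67 in the deletion group.

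The alternatives planned were DESeq2 size factors, DESeq2 1.42.0, no filter, a stricter filter (1 CPM in all libraries of a group and a mean of 20 counts), replicate number as a block, leaving out each library, a log2 fold change of at least 1, the mean of GDel1 and GDel2 from 3 groups, fits on the 2 groups compared alone, limma on log2(TPM + 1), other windows around Praf2, an estimated correlation, and genes of at least 5 CPM for the chromosomes. Added later were the mitochondrial share as a covariate, both libraries of high mitochondrial share left out, chromosomes 6, 8 and Y left out, Praf2 left out of the list of genes around it, and a crossed pairing of replicates.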

Results

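RNA sequencing compared mouse embryonic stem cells carrying a deletion at Praf2 with wildtype cells of the same E14 line. The labels call it a G4 deletion, G4 standing for a G-quadruplex, a folded structure of guanine-rich DNA or RNA. Wildtype had 3 libraries (13360009, 15780833 and 18549005 expected counts), GDel1 had 2 (13538039 and 18762704) and GDel2 had 2 (12316853 and 14434134). The labels do not say whether GDel1 and GDel2 are separate clones, nor whether replicates are separate cultures. Transcripts of the mitochondrial genome took 9.91% of counts in GDel1 replicate 1 (95% Wilson interval 9.89 to 9.92) and 4.83% in GDel1 replicate 2 (4.82 to 4.84). They took 6.19% in GDel2 replicate 1 (6.18 to 6.21) and 9.60% in GDel2 replicate 2 (9.58 to 9.61), while wildtype replicates had 6.89% (6.88 to 6.91), 6.30% (6.29 to 6.31) and 6.30% (6.29 to 6.31). The replicates of GDel1 lay farther apart than those of the other groups, with a chi-square per degree of freedom of 67.8 against 22.3 in GDel2 and 4.79 to 7.23 in wildtype.

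Praf2, which encodes a membrane protein of the prenylated Rab acceptor family, fell in GDel1 and in GDel2. Its level was 28.9 ± 1.56 CPM (SD, n = 3) in wildtype, 9.66 ± 0.564 CPM (SD, n = 2) in GDel1 and 13.6 ± 0.705 CPM (SD, n = 2) in GDel2, and each deletion library was below every wildtype library. GDel1 was 3.00-fold lower than wildtype (log2 fold change -1.59 ± 0.11 SE, adjusted p = 0.00206) and GDel2 was 2.13-fold lower (-1.09 ± 0.11, adjusted p = 2.01e-04). GDel2 retained more Praf2 than GDel1 (0.50 ± 0.12, adjusted p = 0.0183). The gene (ENSMUSG00000031149) spans bases 7728571 to 7731063 of chromosome X in mm10. With GDel1 and GDel2 as 1 group of 4, Praf2 had the lowest p of the 15421 genes (3.59e-05; log2 fold change -1.32 ± 0.16, 2.49-fold lower), yet it missed the threshold after adjustment (0.144). It passed with DESeq2 (adjusted p = 3.67e-08), with the mean of GDel1 and GDel2 from 3 groups (1.21e-04) and with no filter on low counts (0.0410).

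**Figure D1:**
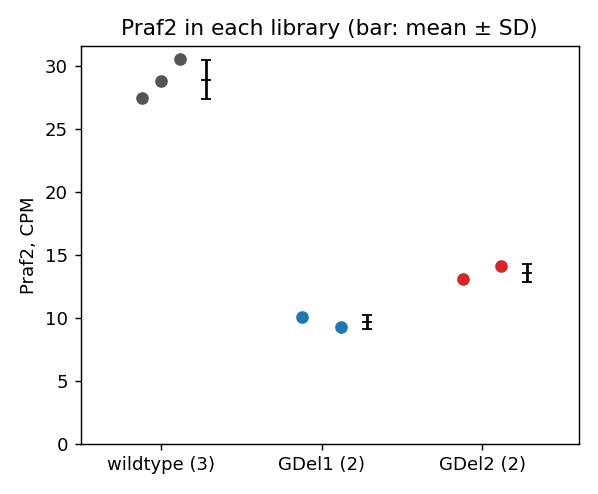
Praf2 in CPM on the y axis for each library, grouped as wildtype, GDel1 and GDel2 on the x axis; points are libraries and bars are the mean with SD. Wildtype libraries lie at 27.5 to 30.6 CPM, GDel1 at 9.26 and 10.1, and GDel2 at 13.1 and 14.1.

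The comparison of genotypes, with all 4 deletion libraries against wildtype, asked which genes changed whichever numbered deletion the cells carried. Replication-dependent histone genes, which supply histones to newly made DNA, were higher as a list: the median of 60 measured genes was 0.58, and 26 were higher when adjusted over the list alone. The camera test gave an adjusted p of 1.89e-14, lost at adjusted p = 0.268 with an estimated correlation. Ribosomal protein genes were higher by a smaller median of 0.26 (2 of 75 higher when adjusted over the list alone; adjusted p = 3.50e-05, and adjusted p = 0.642 with an estimated correlation), although under TPM scaling, which put the median of all genes at -0.16, their median was -0.06. By library, their rise lay in GDel1 (0.33 and 0.49), with GDel2 at 0.04 and 0.05. Wnt target genes, which read out beta-catenin signalling, were lower (median -0.51, 2 of 13 lower when adjusted over the list alone; adjusted p = 2.86e-04, and adjusted p = 0.268 with an estimated correlation). Genes around Praf2, a list that includes Praf2, were also lower (median -0.26, 8 of 32 lower when adjusted over the list alone; adjusted p = 3.04e-04, and adjusted p = 0.268 with an estimated correlation). Without Praf2, 7 of 31 were lower (adjusted p = 9.76e-04). Nuclear RNAs had a median of 0.29 (-0.05 under TPM scaling) with 0 of 16 past the threshold when adjusted over the list alone (adjusted p = 0.0308, and adjusted p = 0.609 with an estimated correlation). That call was lost without wildtype replicate 2 (0.0595), GDel1 replicate 1 (0.125) or GDel1 replicate 2 (0.192). Nuclear RNAs were at 0.39 and 0.61 in the GDel1 libraries and at 0.09 and 0.13 in the GDel2 libraries.

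No single gene passed in this comparison: edgeR called 0 of 15421 genes, with 2930 at an unadjusted p under 0.05 and 309 genes sharing the lowest adjusted p of 0.144. DESeq2 called 865 genes (419 higher and 446 lower), limma on log2(TPM + 1) called 2, and the mean of GDel1 and GDel2 from 3 groups called 3149 (1481 higher and 1668 lower). The other 21 lists did not pass, with adjusted p from 0.0511 to 0.948 and 0 members called over all genes. Among them, 2-cell-like genes had a median of 2.06 (adjusted p = 0.203), mesendoderm genes 0.89 (0.726) and neuroectoderm genes 0.38 (0.0511). Medians lay above 0 while the test pointed down for cholesterol synthesis, Hox, interferon and naive pluripotency genes, and medians just below 0 stood beside means above 0 for formative and primitive endoderm genes.

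The genes that flank Praf2 were examined for changes that reach beyond Praf2. In GDel2, Tfe3, a transcription factor of lysosomal genes, fell to 48.1 ± 2.98 CPM (SD, n = 2) from 99.8 ± 9.39 (SD, n = 3) in wildtype (log2 fold change -1.05, adjusted p = 1.77e-04). Wdr45, an autophagy gene 370 bases from Praf2, fell by 0.89 on the log2 scale (adjusted p = 0.00150), the kinase gene Pim2 by 0.99 (9.63e-04) and the deacetylase gene Hdac6 by 0.67 (0.00189). Eras, which encodes a Ras protein of embryonic stem cells, rose by 0.94 (0.00448). Of 34 genes measured within 500 kb, Praf2 included, GDel2 had 11 lower and 1 higher, with a median of -0.20. Ccdc120 (-0.63), Suv39h1 (-0.55), Tbc1d25 (-0.62), Clcn5 (-0.57), Usp27x (-0.73) and Glod5 (-1.06) were the remaining genes that fell. The calls of Ccdc120 and Tbc1d25 were lost without GDel2 replicate 2 (0.0509 and 0.0501), that of Usp27x without each wildtype replicate (0.0784, 0.0827 and 0.0553) or GDel2 replicate 1 (0.163), and that of Glod5 without wildtype replicate 3 (0.0597), GDel2 replicate 1 (0.0944) or GDel2 replicate 2 (0.0506).

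In GDel1, Praf2 alone of the 34 genes passed over all genes, while 9, Praf2 included, were lower and 1 was higher when adjusted over the list alone. Ccdc120, 651 bases from Praf2, had a log2 fold change of -0.64 (adjusted p = 0.0528), Tfe3 -0.44 (0.0607), Pim2 -0.55 (0.0651), Hdac6 -0.41 (0.0715) and Tbc1d25 -0.53 (0.0607), whereas Wdr45 was at -0.03 (0.903). Wdr45 and Tfe3 differed between GDel2 and GDel1 (-0.86, adjusted p = 0.00339, and -0.62, adjusted p = 0.00450). For the deletion group, 0 of 34 passed with edgeR, 10 had an unadjusted p under 0.05, 8 were lower when adjusted over the list alone, and DESeq2 called 8. Closer to Praf2, within 200 kb, Gpkow, Plp2, Slc35a2, Otud5, Kcnd1, Prickle3, Syp, Pcsk1n, Ppp1r3f, Flicr, Gripap1, Pqbp1, Timm17b and Ccdc22 did not pass in either deletion against wildtype. The strand setting by which overlapping genes were counted is not given in the sources used here.

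**Figure D2:**
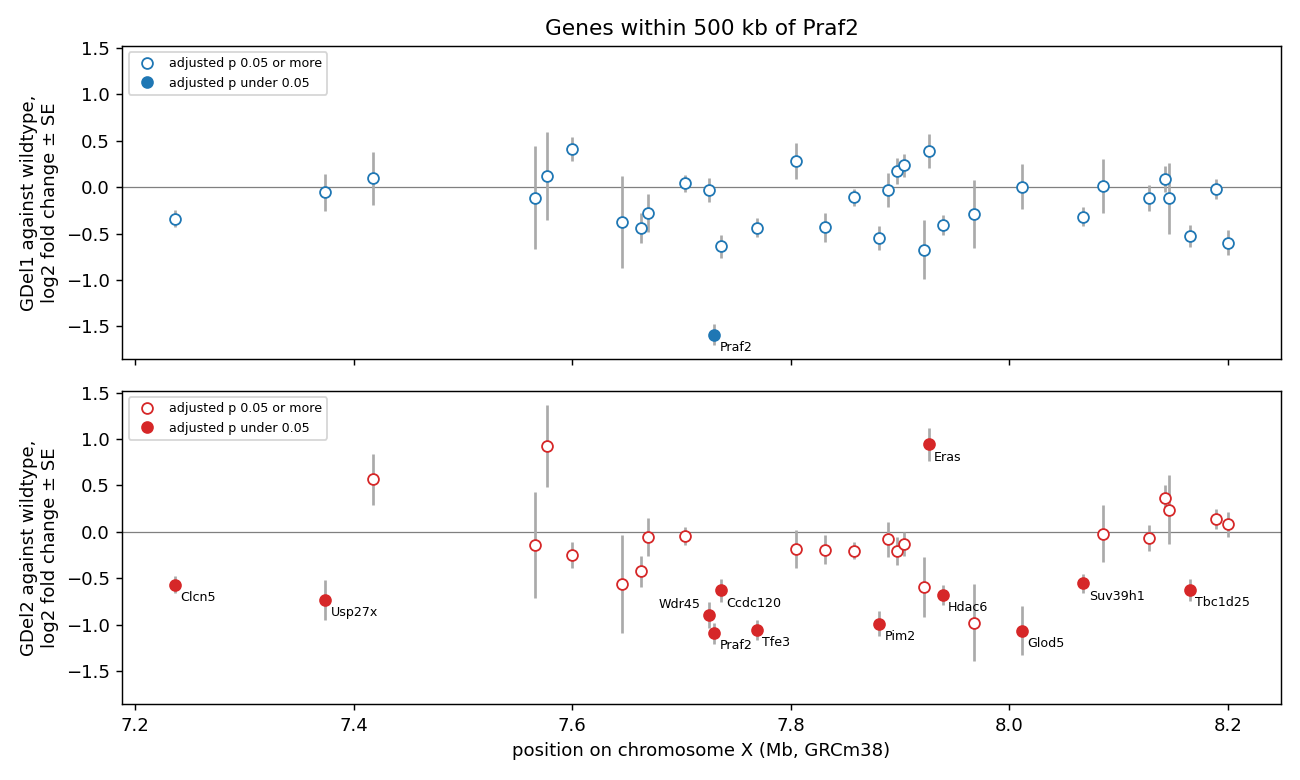
Log2 fold change against wildtype with SE (y axis) for the 34 genes within 500 kb of Praf2 by position on chromosome X (x axis, Mb), GDel1 above and GDel2 below; filled points have an adjusted p under 0.05. GDel1 has 1 filled point, Praf2, and GDel2 has 12, of which Eras alone lies above 0.

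In GDel1, Myh9, the heavy chain of non-muscle myosin II, fell from 176 ± 2.38 CPM (SD, n = 3) to 18.6 ± 3.04 (SD, n = 2; log2 fold change -3.23 ± 0.13, adjusted p = 2.42e-05). The X-linked Xlr3a and Xlr3b, lymphocyte-regulated genes related to synaptonemal complex proteins, fell by 5.06 and 4.08 (adjusted p = 0.00431 and 0.00495), and Xlr4a went from 89 counts in wildtype to 0, at least 19.2-fold lower. These are close paralogs whose reads are hard to tell apart. Rbfox2, a splicing regulator beside Myh9, fell by 0.97 (0.00431), the imprinted transcription factor gene Plagl1 by 2.32 (0.0159), the tetraspanin gene Tspan7 by 2.32 (0.0463) and the imprinted retrotransposon-derived Peg10 by 1.17 (0.0227). Sytl3, a Rab effector of secretion, rose by 1.60 (0.0159), the glycosyltransferase gene Galnt2 by 1.55 (0.0129), and the small structural RNAs Rn7s1 and Rprl3 by 1.09 (0.0227) and 0.98 (0.0327).

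GDel1 had 58 genes past the threshold, 25 higher and 33 lower, 28 of them at least 2-fold. Myh9, Praf2, Xlr3a and Xlr3b were called in all 7 fits that left out 1 library. Without wildtype replicate 1, the adjusted p was 0.0562 for Rbfox2, 0.0629 for Plagl1, 0.0785 for Xlr4a, 0.0976 for Galnt2, 0.103 for Sytl3, 0.132 for Peg10, 0.175 for Rn7s1 and 0.183 for Rprl3 and Tspan7. Those calls were lost without wildtype replicate 2 as well, and those of all but Rbfox2, Plagl1 and Galnt2 without wildtype replicate 3. Without GDel2 replicate 1, Sytl3 (0.0510), Rn7s1, Tspan7, Plagl1 and Xlr4a (each 0.0589) and Rprl3 (0.0601) also missed the threshold. The count stood at 465 with an adjusted p under 0.06 and 1628 under 0.10. It was 4 without wildtype replicate 1, 4 without wildtype replicate 2, 9 without wildtype replicate 3, 14 without GDel2 replicate 1, 2034 without GDel1 replicate 1 and 856 without GDel1 replicate 2. DESeq2 called 866 genes (486 higher and 380 lower), and limma on log2(TPM + 1) called 30 higher and 3220 lower, with the median of all genes at -0.30. GDel1 replicate 1 and GDel2 replicate 2 had the highest mitochondrial shares. Without both, each deletion had 1 library and the spread came from wildtype alone. Without either GDel1 replicate, the spread came from wildtype and GDel2, whose replicates lay closer together. Calls in these fits cannot test the 58 against the spread within GDel1.

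Histone and ribosomal protein genes had the most members past the threshold in GDel1 when p values were adjusted over each list alone, though none passed over all genes. Histone genes had a median of 0.61, with 41 of 60 higher when adjusted over the list alone and 0 over all genes (adjusted p = 7.60e-13, and adjusted p = 0.287 with an estimated correlation). Hist2h2bb had 230, 319 and 326 CPM in wildtype, GDel1 (360 and 279 by replicate) and GDel2. The GDel1 replicates of Hist1h3h lay on both sides of wildtype (331 to 364 CPM), at 529 CPM in replicate 1 and 186 CPM in replicate 2, with GDel2 at 386 and 576 CPM. Ribosomal protein genes had a median of 0.38, with 50 of 75 higher when adjusted over the list alone and 0 over all genes (adjusted p = 5.06e-15, and adjusted p = 0.268 with an estimated correlation); under TPM scaling their median was -0.10, which is 0.20 above that of all genes. Nuclear RNAs had a median of 0.42 (-0.05 under TPM scaling, 0.25 above that of all genes), with 2 of 16 higher, Rn7s1 of the signal recognition particle and Rpph1 of RNase P (0.82, adjusted p = 0.0488), and 7 higher when adjusted over the list alone (adjusted p = 1.96e-04, and adjusted p = 0.276 with an estimated correlation). The call of Rpph1 was lost without each wildtype replicate (0.211, 0.220 and 0.144) or either GDel2 replicate (0.0639 and 0.0565). Factors of R-loops and G-quadruplexes, helicases and RNases that act on these structures, had a median of 0.16 (-0.25 under TPM scaling, 0.05 above that of all genes), with 5 of 26 higher when adjusted over the list alone (adjusted p = 4.58e-04, and adjusted p = 0.268 with an estimated correlation). Among them nucleolin (Ncl) was at 0.37 (adjusted p = 0.0702) and the helicase gene Dhx9 at 0.11 (0.520).

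Lower in GDel1 were Wnt targets (median -0.47, 5 of 13 lower when adjusted over the list alone; adjusted p = 8.77e-04, and adjusted p = 0.268 with an estimated correlation), with Tcf7 at -0.47 (adjusted p = 0.0964) and Znrf3 at -0.41 (0.0633). Clustered protocadherins, cell adhesion genes with promoters bound by CTCF, had a median of -0.33 (0 of 22 when adjusted over the list alone; adjusted p = 4.64e-04, and adjusted p = 0.268 with an estimated correlation). Fibroblast feeder markers were at -0.74 (2 of 8 lower when adjusted over the list alone; 0.00249, and adjusted p = 0.268 with an estimated correlation), with Vim at -0.22 (0.192) and fibronectin (Fn1) at -0.72 (0.266), the latter at -0.32 without GDel1 replicate 1 and -1.28 without GDel1 replicate 2. Genes around Praf2 with Praf2 had a median of -0.11 (adjusted p = 0.0105, and adjusted p = 0.276 with an estimated correlation; adjusted p = 0.0311 without Praf2), a call lost without GDel1 replicate 1 (0.0785). Hox genes were at -0.69 (2 of 9 lower when adjusted over the list alone; 0.0105, and adjusted p = 0.287 with an estimated correlation), lost without GDel1 replicate 1 (0.330) or with the stricter filter on low counts (0.111). For 2-cell-like genes the median was -0.71 (0 of 12 when adjusted over the list alone; 0.0191, and adjusted p = 0.268 with an estimated correlation), lost without GDel1 replicate 2 (0.0910) or with the stricter filter (0.310). Under TPM scaling the protocadherin, Hox and 2-cell-like medians lay above that of all genes by 0.02, 0.12 and 0.19. These values cannot show a reversal, since log2(TPM + 1) draws the changes of genes of low TPM towards 0. The 2-cell-like median went from -0.71 to -0.11 in GDel1 and from 3.01 to 0.82 in GDel2.

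The other 16 lists did not pass in GDel1, with adjusted p from 0.0580 (neuroectoderm) to 0.908 (interferon). Of 36 imprinted genes, Plagl1 and Peg10 fell and none rose (adjusted p = 0.150). Naive pluripotency genes had a median of -0.01 (0.851) and stress response genes a median of 0.00 (0.828), with the chaperone gene Hspa5 at 0.50 (adjusted p = 0.0528). Mitochondrially encoded genes had a median of 0.33 (0.0678), at 0.68 in replicate 1 and -0.30 in replicate 2. CTCF and cohesin factors had a median of 0.04 (0.699). The median and the test differed in sign for interferon genes, p53 targets and stress genes. For p53 targets and stress genes the median and the mean also differed in sign.

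**Figure D3:**
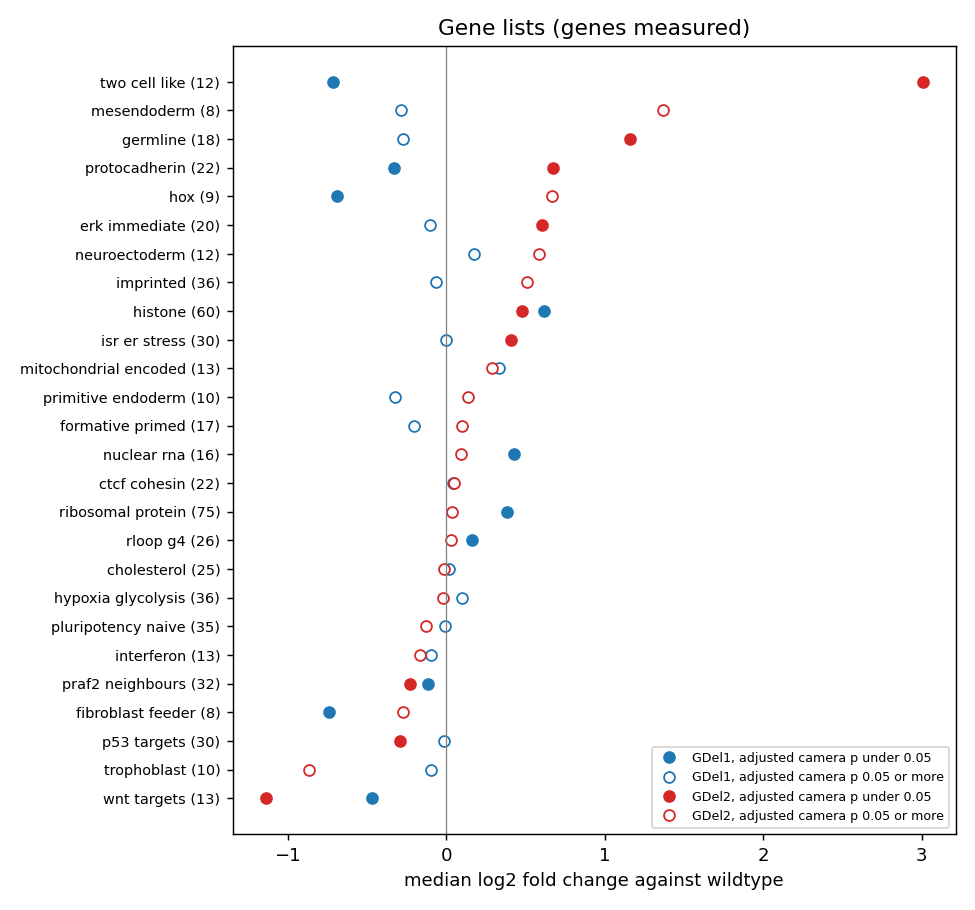
Median log2 fold change against wildtype (x axis) of each of the 26 lists (y axis, genes measured in parentheses) in GDel1 (blue) and GDel2 (red); filled points have an adjusted camera p under 0.05. The 2-cell-like list lies at 3.01 in GDel2 and -0.71 in GDel1, and histones at 0.48 and 0.61.

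GDel2 had lost the transcripts of several genes on the Y chromosome. Uty, an X-Y paralog of a histone demethylase, had 0 counts in both GDel2 libraries, at least 877-fold lower than its wildtype level of 99.8 CPM. Uba1y also had 0 counts (at least 57.8-fold lower), the translation factor gene Eif2s3y had 1 (2106-fold lower, 95% interval 378 to 83200) and the helicase gene Ddx3y had 4 (416-fold lower, 162 to 1526). Ccnd2, a cyclin of the transition from G1 to S phase, rose from 0.302 to 19.8 CPM (log2 fold change 5.97, adjusted p = 3.92e-06). The imprinted genes Plagl1 (18.9 to 300 CPM; 3.99), Mest (30.7 to 273 CPM; 3.15), H19 (4.78) and Nnat rose, Nnat from 0 to 95 counts and so at least 58.3-fold, while 9 of the 36 imprinted genes fell.

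Cd180, a Toll-like receptor relative, also rose in GDel2 (4.77). The aldehyde oxidase gene Aox3 fell from 55.6 to 0.726 CPM (-6.26). In all, 5099 genes passed, 2688 higher and 2411 lower, 1662 of them at least 2-fold. The count was 3391 without wildtype replicate 2. Of the genes, 4301 were not placed on chromosomes 6, 8 or Y, which includes genes without a position. The self-test on simulated data with the group means called 78.0% of genes set 2-fold apart in GDel2, 71.4% in GDel1 and 52.8% in the deletion group.

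Genes of the 2-cell-like state, a transient state resembling the early embryo, rose together in GDel2: 11 of 12 were higher, with a median of 3.01 (adjusted p = 7.23e-05, and adjusted p = 0.268 with an estimated correlation). Zscan4f rose from 1.03 to 4.72 CPM (2.19), and Gm8300 and Gm5662 rose by 4.38 and 3.35, all at low levels and in families of close paralogs. Zscan4c rose by 2.72 (adjusted p = 0.00896), a call lost without GDel2 replicate 2 (0.0563). Wnt targets moved the opposite way, with 8 of 13 lower and a median of -1.14 (9.84e-04, and adjusted p = 0.268 with an estimated correlation): Lef1 fell by 2.79, Sp5 by 2.46, Cdx2 by 2.10 and Apcdd1 by 1.90. Germline genes had 8 of 18 higher and 3 lower (median 1.16; 0.00475, and adjusted p = 0.268 with an estimated correlation). The meiotic genes Stra8 and Sycp3 rose by 3.91 and 2.04 while the piRNA pathway gene Rnf17 fell by 1.73.

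Clustered protocadherins had 10 of 22 higher and 2 lower in GDel2 (median 0.67; adjusted p = 0.00420, and adjusted p = 0.268 with an estimated correlation), among them Pcdhga6 (2.14), Pcdhga9 (1.25) and Pcdhgb5 (1.22). Histone genes had 15 of 60 higher and 0 lower (median 0.48; 1.54e-04, and adjusted p = 0.607 with an estimated correlation), with Hist1h3f at 0.68 and Hist1h1a at 0.65. Genes responsive to ERK, the kinase below the inhibited MEK, had 11 of 20 higher and 2 lower (median 0.61; 0.0147, and adjusted p = 0.274 with an estimated correlation). Etv4, Spry4 and Ccnd1 rose by 1.70, 1.34 and 0.62 and Etv1 fell by 1.25; the list missed the threshold without GDel1 replicate 1 and GDel2 replicate 2 together (0.0663). The stress response list had 13 of 30 higher and 3 lower (median 0.41; 0.00527, and adjusted p = 0.268 with an estimated correlation), with Mthfd2 at 1.54, Herpud1 at 1.32, Vldlr at 1.76 and Asns at 0.70. Of these 13 genes, 7 lie on chromosomes 6 or 8 or on chromosome 11 below 60 Mb. The p53 targets had 10 of 30 lower and 3 higher (median -0.29; 0.0272, and adjusted p = 0.276 with an estimated correlation), with Psrc1 at -0.87, Dcxr at -1.11 and the stress sensor gene Sesn2 at -0.79; this call was lost without GDel2 replicate 1 (0.0533) or wildtype replicate 3 (0.0556), or with replicate number as a block (0.0691). Of the 3 higher p53 targets, 2 lie on those segments. Genes around Praf2 with Praf2 had 11 of 32 lower and 1 higher (median -0.23; 0.00249, and adjusted p = 0.268 with an estimated correlation), and without Praf2 10 of 31 lower (0.00527).

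The other 17 lists did not pass in GDel2, though many of their members did. Imprinted genes had 16 of 36 higher and 9 lower (median 0.51; adjusted p = 0.0511), with the noncoding RNA Rian up by 1.19. Mesendoderm genes had 5 of 8 higher and 1 lower (0.0580), among them Eomes (1.94) and Bmp4 (1.61), and neuroectoderm genes 4 of 12 (0.0926), among them Gap43 (4.41), Tubb3 (1.49) and Sox1 (1.26), the last 2 on chromosome 8, while Sox21 fell by 2.78. Naive pluripotency genes split, with 10 of 35 higher and 11 lower (0.673): Zfp42 and Lin28a rose by 1.15 and 0.95, and Gbx2 and Tfcp2l1 fell by 1.36 and 0.81. Formative genes also split (7 of 17 higher and 5 lower; 0.685), with Sox4 and Lin28b up by 3.31 and 2.09. Trophoblast genes had 6 of 10 lower and 3 higher (0.203), with Gata2 and Gata3 down by 1.80 and 2.53, and Hox genes 5 of 9 higher (0.244), with Hoxd13 up by 2.08.

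Among factors of R-loops and G-quadruplexes 7 of 26 were higher and 5 lower in GDel2 (adjusted p = 0.763): the repair genes Fancd2 and Brip1 rose by 0.90 and 0.73. CTCF and cohesin factors had 2 of 22 higher and 2 lower (0.851), with the heterochromatin protein gene Cbx3 up by 0.79. Cholesterol genes had 4 of 25 higher and 3 lower (0.851), with Msmo1 up by 0.87 and Sqle down by 1.04. Hypoxia and glycolysis genes had 9 of 36 higher and 6 lower (0.804), with Pdk1 up by 1.02 and Aldoc down by 1.11. Interferon genes had 3 of 13 higher and 4 lower (0.851), with Bst2 up by 1.96 and Oas1a down by 1.32. Primitive endoderm genes had 3 of 10 each way (0.713), with Col4a1 up by 1.39 and Apoe down by 1.30, and feeder markers 2 of 8 higher and 3 lower (0.790), with Vim down by 0.88. Ribosomal protein genes had 3 of 75 higher and 4 lower (0.846), nuclear RNAs 1 of 16 lower (0.790), and mitochondrially encoded genes 1 of 13 lower (0.804; medians of -0.15 in replicate 1 and 0.56 in replicate 2). Of the higher genes, 6 of 9 for hypoxia and glycolysis, 2 of 2 for CTCF and cohesin, 3 of 3 for ribosomal proteins, 2 of 4 for cholesterol and 3 of 7 for R-loops and G-quadruplexes lie on chromosomes 6 or 8 or on chromosome 11 below 60 Mb. For interferon and for primitive endoderm it was 1 of 3 each. Median and mean differed in sign for cholesterol, feeder, hypoxia and interferon genes.

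Genes on chromosomes 6 and 8 were higher in GDel2 as sets. The median gene on chromosome 6 was 1.42-fold above wildtype (log2 0.51, 342 of 666 genes higher and 43 lower; adjusted camera p = 5.77e-13, and adjusted p = 0.00595 with an estimated correlation). On chromosome 8 it was 1.36-fold above (0.44, 368 of 724 higher and 40 lower; 9.22e-14, and adjusted p = 0.0718 with an estimated correlation). GDel2 replicates 1 and 2 were at 0.50 and 0.53 on chromosome 6 and at 0.47 and 0.43 on chromosome 8, and the GDel1 replicates lay between -0.03 and 0.03 on both. Medians of the other autosomes in GDel2 ran from -0.13 on chromosome 7 to 0.11 on chromosome 11, and X was at 0.03. The Y set was lower (adjusted camera p = 2.26e-06, and adjusted p = 0.0966 with an estimated correlation), except for the Y-linked gene model Gm20775 with 377 counts. In GDel1 none of the 6 Y genes passed the threshold: Uty was at 0.17, Uba1y at 0.18, Eif2s3y at 0.32 and Ddx3y at 0.53 on the log2 scale. Zfy1 was at -1.26 (adjusted p = 0.114; 17 counts against 62 in wildtype) and Gm20775 at -0.57, with 200 and 31 counts in the GDel1 replicates. Chromosome 13 was the only one called in GDel1 (median 0.12; adjusted camera p = 0.00640, and adjusted p = 0.688 with an estimated correlation), and its median was 0.09 without the 49 histone genes it holds.

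**Figure D4:**
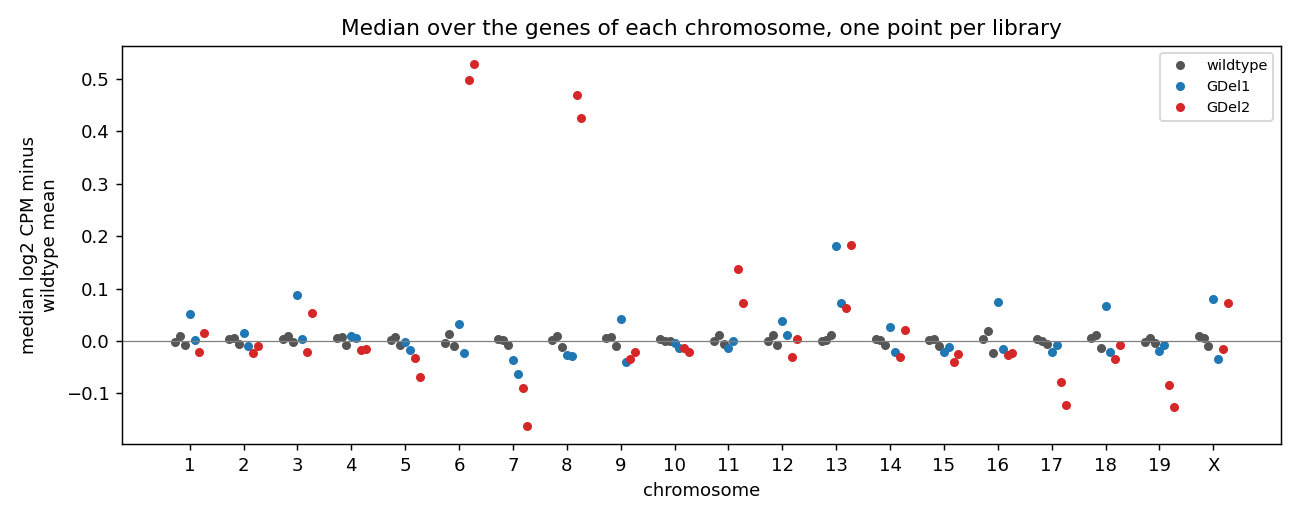
Median log2 CPM minus the wildtype mean (y axis) of the genes of each chromosome (x axis) in each library, coloured by group. GDel2 libraries lie at 0.43 to 0.53 on chromosomes 6 and 8, and GDel1 libraries between -0.03 and 0.03.

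**Figure D5:**
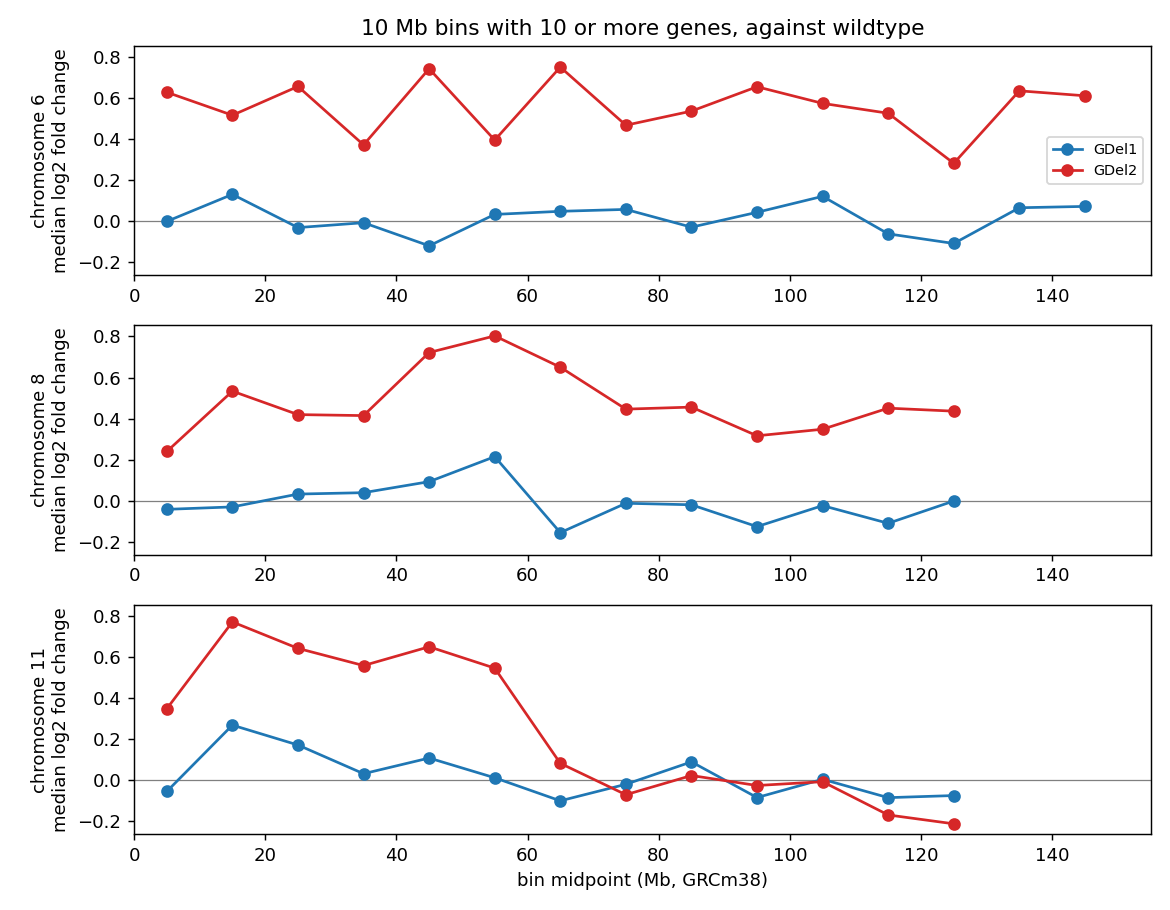
Median log2 fold change against wildtype (y axis) in 10 Mb bins with 10 or more genes along chromosomes 6, 8 and 11 (x axis, bin midpoint in Mb) for GDel1 (blue) and GDel2 (red). The 28 bins of chromosomes 6 and 8 lie between 0.24 and 0.80 in GDel2.

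GDel2 and GDel1, which share a genotype label, differed directly in 4268 genes, 2289 higher and 1979 lower in GDel2. Plagl1 was 6.31 higher on the log2 scale, Ccnd2 6.63 and Cd180 4.55, the growth factor gene Tgfa was 35.4-fold higher (95% interval 11.7 to 175), and Myh9 was 2.29 higher, having fallen less than in GDel1. Uty was at least 984-fold lower in GDel2, Ddx3y -9.15, Aox3 -5.66 and Sytl3 -2.54. The count was 2805 without GDel2 replicate 1 and 2602 without GDel2 replicate 2.

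A set of genes changed in both deletions against wildtype. Of 33 genes called in both, 26 moved the same way, 9 up and 17 down. Besides Praf2 they included Myh9 (-3.23 in GDel1 and -0.94 in GDel2), Rbfox2 (-0.97 and -0.53), the ubiquitin ligase adaptor gene Klhl13 (-0.82 and -1.43), and the axon guidance gene Rgma (-0.86 and -1.71). The dopa decarboxylase gene Ddc rose in both (0.70 and 1.75), as did Emp1 (0.89 and 1.29), which under TPM scaling was at -0.16 in GDel1, where the median of all genes was -0.30. Independent lists of these sizes would share 9.52 genes in the same direction. Among the 33, the direction in GDel1 went with that in GDel2 (Fisher's exact test, 2-sided p = 0.00281). Both contrasts use the same wildtype libraries, which by itself makes fold changes agree. Over all genes they correlated at 0.17 and 61.4% had the same sign, against means of 0.38 and 62.8% in 20 simulations with no change in either group, while their covariance was 0.0761 against 0.0368. Plagl1, which fell in GDel1 and rose in GDel2, was among 7 genes called in opposite directions. The GDel1 calls of Klhl13, Rgma, Ddc and Emp1 were lost without each wildtype replicate (adjusted p of up to 0.220) or GDel2 replicate 1 (0.0589 to 0.0639), those of Klhl13, Rgma and Ddc also without GDel2 replicate 2 (0.0529 to 0.0565), and that of Rbfox2 without wildtype replicates 1 (0.0562) or 2 (0.0703). The shared count was 3 without wildtype replicate 1, 3 without replicate 2, 7 without replicate 3, 7 without GDel2 replicate 1, 679 without GDel1 replicate 1 and 437 without GDel1 replicate 2.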

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

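Chosen only after the result was seen were the tests of low depth, of Uty against Kdm6a, of 2 active X chromosomes, of scaling and of shared variation on chromosomes 6 and 8, of shared variation near Praf2, of bins without the chromosome 11 segment, and of splits for the count of 0 genes.

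Y-linked genes differed between the deletions. GDel2 held 5 counts over the Y-linked genes at 0 to 4 counts. The wildtype level and the depth of GDel2 gave 6606, so low depth is excluded. Assignment of Uty reads to its X-linked copy Kdm6a is argued against, since Kdm6a changed by -0.117 CPM per CPM of Uty lost in the GDel2 library where it was higher. For the X-linked copies together this gain was 0.556 in replicate 2 and -0.246 in replicate 1, so reassignment cannot be told apart from loss for the remaining genes, as the replicates disagree. The X-linked copies were also 283 and 109 CPM above wildtype in the GDel1 replicates, against 138 and -61.1 CPM in GDel2 replicates 2 and 1, so such a gain is not tied to Y loss. A second active X is argued against, as the median X-linked gene was at 0.0292 (95% bootstrap interval -0.03 to 0.08). Loss of the Y chromosome in the cells of GDel2 may account for the pattern, as a hypothesis that was not tested, and DNA was not analysed here. The Y-linked gene model Gm20775, at 14.2 CPM in GDel2 against 12.3 in wildtype, did not fall. It speaks against loss of the whole chromosome unless its reads come from elsewhere, which was not tested. Gm20775 starts at base 10640936, while the other measured Y-linked genes lie between bases 725207 and 1286628.

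Genes on chromosomes 6 and 8 were higher in GDel2. The smallest excess over the other autosomes under TMM, DESeq2 size factors and TPM was 0.342, on log2(TPM + 1). Comparing scalings decides nothing here, since a factor per library moves all chromosomes alike and cancels in the excess. Variation shared by GDel1 replicate 1 and GDel2 replicate 2 is argued against. The excess was 0.498 in GDel2 replicate 1 and -0.02 in GDel1 replicate 1. An extra copy of each whole chromosome remains a hypothesis: 89.3% of the 28 bins lay above the 95th percentile of bins on other autosomes (0.34), just under the 90% set beforehand. The bins on other autosomes include 6 of chromosome 11 below 60 Mb, themselves at 0.35 to 0.77, and without them all 28 lay above the percentile (0.23). For comparison, 3 copies in place of 2 would give 0.585 in every cell against medians of 0.51 and 0.44. It cannot be told apart from other causes, as RNA alone does not count copies.

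Genes near Praf2 were lower in GDel2, 11 of 34 with Praf2. Apart from Praf2, 8 genes were also called lower in the fit without GDel2 replicate 1. For these, variation shared by GDel1 replicate 1 and GDel2 replicate 2 is argued against, since in the library left out their median was -0.558 on the log2 scale, with each gene at -0.455 or below and wildtype libraries at -0.13 or above. This does not cover Usp27x and Glod5. A chance position remains open: 7.56% of runs of 34 neighbouring genes elsewhere held as many lowered genes, and 12.3% had a median as low. An effect of the deletion on neighbouring genes was not tested apart from other differences between the cells, which the design does not separate.

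The count of 0 genes for the deletion group cannot be tested by splits: each of the 35 splits of the 7 libraries into 4 and 3 had to give as many, and the highest of the others was 0. At an unadjusted p under 0.05 the real split gave 2930 genes and 3 of 35 splits gave as many, the highest other being 4066 for the 3 wildtype libraries with GDel1 replicate 2 and another 3268 for them with GDel1 replicate 1. Chance is not excluded for this count, and both of those splits keep the 2 GDel2 libraries together against wildtype, a structure of the samples.

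A sample stood far from the others in 2 of the 92 named genes, no more than the about 1 in 20 groups that chance gives. The rule took the 4 deletion libraries as 1 group, although GDel1 and GDel2 differ from each other. Kcnd1 was at 9.94 CPM in GDel2 replicate 1 against 7.24 to 7.52 in the other deletion libraries, with wildtype at 9.90 to 9.98. Otud5 was at 36.8 CPM in GDel2 replicate 2 against 41.3 to 42.2, with wildtype at 44.0 to 46.8.

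GDel2 differed from GDel1 in 4268 genes, among them 42 listed here, by the edgeR contrast of these groups. Higher in GDel2, as log2 fold changes, were Praf2 (0.50), Xlr3a (4.09), Xlr3b (2.45), Myh9 (2.29), Tspan7 (1.95), Plagl1 (6.31), Ccnd2 (6.63), Cd180 (4.55), Ccnd1 (0.57), Rian (1.01), Asns (0.68), Bmp4 (1.43), Ncam1 (0.47), Sparc (0.56), Tead4 (0.53), Zscan4f (2.91), Zscan4c (3.28) and Znrf3 (0.69). Nnat was 113-fold higher (95% interval 19.9 to 4525), H19 at least 31.8-fold and Tgfa 35.4-fold (11.7 to 175). Lower in GDel2 were Tfe3 (-0.62), Ccdc22 (-0.66), Wdr45 (-0.86), Sytl3 (-2.54), Galnt2 (-0.82), Rn7s1 (-0.87), Ddx3y (-9.15), Aox3 (-5.66), Hmgcs1 (-0.68), Vim (-0.66), Rnf17 (-1.93), Stk31 (-1.05), Pkm (-0.43), Xaf1 (-0.83), Malat1 (-0.43), Trp53inp1 (-0.88), Tfcp2l1 (-0.58) and Tfap2c (-0.76). Uty was at least 984-fold lower, Uba1y at least 63.1-fold and Eif2s3y 2621-fold (470 to 103500). Plagl1 and Sytl3 were called in opposite directions against wildtype.

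Some of these 42 differences were lost when 1 library was left out. Without GDel2 replicate 2 the adjusted p was 0.0530 for Ccdc22, 0.0740 for Galnt2, 0.0685 for Xaf1, 0.0699 for Pkm, 0.0623 for Malat1, 0.0728 for Tfcp2l1, 0.0553 for Sparc, 0.109 for Tfap2c and 0.0526 for Zscan4c. Without GDel2 replicate 1 it was 0.0675 for Ccdc22, 0.0658 for Xaf1, 0.0689 for Malat1, 0.0799 for Sparc and 0.138 for Tead4. Without GDel1 replicate 2 it was 0.0531 for Tfap2c, and without wildtype replicate 2 it was 0.0513 for Malat1. The count was 2805 without GDel2 replicate 1 and 2602 without GDel2 replicate 2.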

How the results depend on the processing

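Chosen after the data were seen were the mitochondrial share as covariate, leaving out both high-mitochondrial libraries, leaving out chromosomes 6, 8 and Y, leaving Praf2 out of its list, and the crossed pairing. A lone library left in a group is assumed to vary like the other groups. The cause was not tested unless stated. The count for the deletion group (0) was 865 with DESeq2, 1 with no filter, 2 with limma on log2(TPM + 1), and 3149 as the mean of GDel1 and GDel2, which leaves their spread out of the error; it was 0 to 0 with 1 library left out. Praf2 in that comparison passed at -1.32 with DESeq2, -1.33 with no filter and -1.34 as the mean, and ranged from -1.43 to -1.22 with 1 library left out. The count near Praf2 (0) was 8 with DESeq2, 1 with no filter and 10 as the mean. GDel1 (58) had 866 genes with DESeq2, 2357 with no filter, 1 (Myh9) with replicate number as a block, 28 at a log2 fold change of at least 1, 13 on the 2 groups alone, 3250 with limma, 3488 with the covariate, 4262 without both high-mitochondrial libraries and 25 without chromosomes 6, 8 and Y; it ranged from 4 to 2034 with 1 library left out. GDel2 (5099) had 2296 with the block, 1662 at a log2 fold change of at least 1 and 2604 with limma, and ranged from 2643 to 6578. GDel2 against GDel1 (4268) had 2235 with the block and 1676 at a log2 fold change of at least 1, and ranged from 2602 to 5617; the crossed pairing gave 3610. The shared count (26) was 309 with DESeq2, 921 with no filter, 1 with the block, 4 at a log2 fold change of at least 1, 8 on the 2 groups alone, 619 with limma, 1556 with the covariate, 1371 without both high-mitochondrial libraries and 14 without chromosomes 6, 8 and Y, and ranged from 3 to 679. Praf2 was at -1.54 in GDel1 with the block (adjusted p = 0.141). Deviations of same-numbered GDel1 and GDel2 libraries correlated at -0.454 across genes, which are not independent replicates. With 2 libraries per group, pairs of unlike number are then at 0.454 by construction. The sign therefore cannot decide whether replicate numbers pair the samples. In GDel1 Praf2 ranged from -1.64 to -1.53 with 1 library left out, and in GDel2 all alternatives kept its call. List calls of camera (24 of 78) fell to 0 with an estimated correlation, and chromosome calls (4) to 1. For 2-cell-like genes in GDel2 the estimate was -0.07, below the preset 0.01, so correlation does not account for that loss. With fry, ribosomal protein genes and nuclear RNAs in the deletion group (each adjusted p = 0.251) missed the threshold. So did Hox genes in GDel1 (0.0585) and histones in GDel2 (0.0961). The other list calls stayed past it, such as 2-cell-like genes in GDel2 (2.31e-04).

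Of 6868 values of 411 results for named genes, 5814 kept direction and side of the threshold, 578 were no longer past it, 279 came past it, 183 not past it changed sign, and 14 were reversed. Reversed in GDel1 with limma on log2(TPM + 1) were Pds5a (-0.58), Malat1 (-0.61) and Emp1 (-0.16), the last above the median of all genes there (-0.30), and Pkm in GDel2 against GDel1 (0.00901). Without both high-mitochondrial libraries Hist1h3h (-0.87), mt-Co1 (-0.48), mt-Nd1 (-0.77), Rn7sk (-0.34) and Rpsa (-0.38) reversed in GDel1 and Rpsa (0.20) in GDel2 against GDel1, and with the covariate mt-Nd1 (-0.31) in GDel1. With 1 library left out Rpsa ranged from -0.40 (without GDel1 replicate 1) to 0.42 in GDel1, and in GDel2 against GDel1 Rpsa ranged from -0.50 to 0.31 and Rn7sk from -0.60 to 0.44, each highest without GDel1 replicate 1.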

Other observations

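Genes on the first 60 Mb of chromosome 11 were higher in GDel2, a segment chosen after its values were seen. The median of 318 genes there was 0.54, with 179 higher and 12 lower, at 0.54 and 0.51 in the GDel2 libraries and 0.05 in GDel1. The 783 genes from 60 to 130 Mb had a median of -0.05, with 110 higher and 142 lower.

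Several genes called in GDel1 lie near each other. Of 52 calls with a position, 15 had another within 1 Mb, against a mean of 4.27 and a highest of 16 in 10000 random draws of tested genes (permutation test, one-sided p = 9.0e-04), a test chosen after the result was seen. They include Rbfox2 and Myh9 on chromosome 15, the paralogs Xlr3a, Xlr3b and Xlr4a on X, and Sytl3 and Gm2808 on chromosome 17.

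Histone genes on chromosome 13 had medians of 0.67 in GDel1 and 0.48 in GDel2. By library, the whole histone list was at 0.55 and 0.69 in GDel1 and at 0.34 and 0.63 in GDel2.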
